A study of Mus musculus with 4 samples.

How the data were processed

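Poly(A) RNA was sequenced from 4 libraries of mouse bone marrow-derived monocytes in osteoclast culture, 2 control and 2 Piezo1 knockout, all with the same batch value in the labels. Per the labels' protocols, non-adherent marrow cells were carried forward into M-CSF, RNA was extracted on columns with removal of genomic DNA, and libraries were made with a poly(A) selection module and the xGen RNA kit and sequenced as paired-end reads on a NextSeq instrument. The submitters' processing notes name STAR, featureCounts from Subread, edgeR and the mouse build mm10, also called GRCm38, and give no versions. The authors deposited 1 table of 12799 genes with a normalised signal per library, read here as CPM, gene reads relative to a scaled library size.

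That reading came from the values. Every value of a deposited column was a whole multiple of the column's smallest positive value, with 100% of values within 0.001 reads of a whole number and a largest deviation of 1.1e-09, which gives back whole reads. CPM computed from those reads with TMM scaling in edgeR matched the deposited signal to within 4.9e-11. The recovered totals were 15320308 and 14122118 reads in the controls and 14997205 and 18897927 in the knockouts, with TMM factors of 1.01, 1.01, 1.01 and 0.97. The authors' filter on low genes, the annotation release and the strand setting of the counting are not given in the sources used here. Overlapping and antisense genes can therefore share reads, and genes of multigene families are reported as uncertain. The libraries were compared in pairs by a chi-square test of reads over genes, and every pair differed beyond sampling noise. Poisson intervals and floors cover counting error only, since the labels mention no molecular identifiers.

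The main test was limma with an intensity trend on log2(CPM + 0.5) for the 11781 genes at 1 CPM or more in at least 2 libraries, with genotype as the sole term, 2-sided, and Benjamini-Hochberg adjustment. A fold change on this scale understates the change of low genes. Residual degrees of freedom were 7.52 after moderation, of which 5.52 came from the prior. With 2 libraries against 2, 3758 tested genes (31.9%) had groups that did not overlap, and chance gives 33.3%. Values are means ± SD over 2 libraries. Before the data were examined, the gene lists, the tests, the alternatives and the rule for named genes had been fixed. Of 40 lists, the 35 with 5 or more tested members entered limma's camera test with a preset correlation of 0.01, adjusted over those lists, and members were also adjusted over the list alone. Of the marker lists too small to test, B cells had 3 tested members, T and NK cells 2, mast cells and basophils 0 and endothelial cells 4, and the sex-linked list had 1, Xist, at 346 ± 53.3 CPM in controls and 283 ± 8.06 CPM in knockouts.

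Named were Piezo1, 12 landmark osteoclast genes, up to 12 genes in each direction with the largest fold change among those with an adjusted p under 0.05, a mean of 5 CPM or more and no overlap between groups, and up to 4 members with the smallest p of each called list and of 6 further lists. In a direction with fewer than 6 such genes, the 6 with the smallest p were named whether or not they passed. Of the genes taken by this rule, 1 is counted in the totals but not reported here. Genes outside this rule are named where a list or region was singled out, and were chosen after their values were seen. Alternatives were other pseudocounts, filters, scalings and variance models, the replicate number as a block, each library left out, edgeR and DESeq2 on the recovered reads, and for lists an estimated correlation and fry. A scan of 10-Mb tiles for an excess of genes at an unadjusted p under 0.01 and a grouping of genes into 5 families were added later. Positions came from GENCODE release M21 on GRCm38, in which 12704 of the 12799 symbols were found. The release may differ from that of the authors.

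The steps were tested on simulated reads for 11761 genes of this comparison. limma recovered 50.0% of 66 genes changed 1.5-fold, 82.1% of 67 changed 2-fold and 96.9% of 64 changed 4-fold, with 16 calls among 11532 unchanged genes. camera recovered a lysosome list shifted by 0.5 on the log2 scale with the preset correlation (adjusted p = 1.52e-35) but not with an estimated one (adjusted p = 0.163), and called 1 other list of the 35. The reads of each gene were simulated independently, so this step does not test the preset correlation on lists whose members vary together. The scan of chromosomal tiles recovered a planted tile (adjusted p = 0.00112) and called a tile in 2 of 100 shuffles of gene positions. Versions were R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.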

Results

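The series measured poly(A) RNA in mouse bone marrow-derived monocytes that had been driven toward the osteoclast, the multinucleated cell that resorbs bone. Cells from female mice were grown for 3 days with the growth factor M-CSF at 30 ng/mL and the osteoclast-inducing cytokine RANKL at 50 ng/mL, a time at which precursors are still maturing. Control cells carried Piezo1 alleles flanked by loxP sites and no recombinase (n = 2), and knockout cells carried the same alleles with the Csf1r-iCre transgene, which removes the flanked segment in cells of the monocyte lineage (n = 2). The design text calls the libraries biological replicates. Read totals recovered from the normalised values were 15320308 and 14122118 for control 1 and control 2, and 14997205 and 18897927 for knockout 1 and knockout 2, so that 1 read was worth between 0.0544 and 0.0700 CPM, the library-scaled unit of every level given here. Mitochondrially encoded transcripts took 3.13% and 2.27% of the signal in the controls and 1.38% and 2.74% in the knockouts. Pearson correlations between libraries, computed across genes, which are not independent replicates, were 0.990 to 0.992.

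The comparison asks which transcripts differ when Piezo1, a cation channel opened by membrane stretch, is removed from osteoclast precursors. Because the controls carried no recombinase, effects of the Csf1r-iCre transgene itself cannot be told apart from those of Piezo1 loss. Piezo1 itself (ENSMUSG00000014444.17; chromosome 8, 122481698 to 122551329, minus strand, GRCm38, protein-coding) fell from 407 ± 32.2 CPM in the controls to 58.6 ± 3.41 CPM in the knockouts (SD, n = 2 each), which is 14.4% of the control level. The log2 fold change was −2.79 (SE 0.10, 95% confidence interval −3.02 to −2.55), with a limma Benjamini-Hochberg adjusted p of 8.23e-05. Both knockout libraries lay below both controls. Which exons are flanked by loxP sites is not given in the sources used here, so the remaining 14.4% cannot be divided between undeleted cells and transcript from outside the deleted segment.

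Beyond Piezo1, the genes that fell in the knockout libraries included Tdrd9, Timp3 and Thbs1, and those that rose included Clic5 and Rcan2. Of 11781 genes tested with limma, 5 rose and 14 fell at an adjusted p under 0.05, and 16 of these 19 had a log2 fold change of at least 1 in size. At an unadjusted p under 0.05 there were 159 higher and 418 lower genes. Together these were 577 of 11781, no more than that threshold would pass by chance, so their number at that threshold is no sign of further changed genes. At an unadjusted p under 0.01, 170 of 11673 genes with a position passed (1.46%). Without the called genes the share was 1.3%, also above that threshold, so further changed genes are not excluded. edgeR, run on the recovered reads, called the same 19 genes, and DESeq2 called 66 that included all 19.

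The largest fall was that of Tdrd9, an RNA helicase of the germline piRNA pathway, from 111 ± 8.36 to 2.75 ± 1.56 CPM (log2 fold change −5.18, SE 0.29, adjusted p = 0.000848; chromosome 12, 111971559 to 112068854). Clba1, which encodes a clathrin-binding protein and lies 0.74 Mb from Tdrd9 (chromosome 12, 112808937 to 112816252), fell from 38.8 ± 0.28 to 4.09 ± 0.37 CPM (log2 fold change −3.10, SE 0.14, adjusted p = 0.00029). Inhba, the subunit of activin A, fell from 48.1 ± 11.7 to 15.4 ± 0.04 CPM (log2 fold change −1.59, adjusted p = 0.0236), and Pappa, a protease that cleaves insulin-like growth factor binding proteins, fell from 20.3 ± 1.60 to 7.21 ± 0.03 CPM (−1.43, adjusted p = 0.0224). Timp3, a matrix-bound inhibitor of metalloproteinases, fell from 93.2 ± 6.41 to 36.1 ± 3.80 CPM (−1.36, adjusted p = 0.00883). Thbs1, which encodes thrombospondin-1 and was the most abundant of these, fell from 418 ± 10.4 to 193 ± 34.7 CPM (−1.12, adjusted p = 0.0284). The collagen gene Col8a1 (−1.08), Ccn2, a matricellular growth factor (−0.99), and the fibrillin gene Fbn1 (−0.78) fell with adjusted p of 0.0236, 0.0236 and 0.0357. The coiled-coil genes Ccdc28b (−1.32, adjusted p = 0.0357) and Ccdc85c (−1.15, adjusted p = 0.0389) also fell, as did Klra17, a member of the Ly49 receptor family (−0.99, adjusted p = 0.0376), whose reads can be shared with near-identical paralogs. In the same libraries the marker transcripts of stromal, fibroblast and osteoblast cells had a median log2 fold change of −0.57.

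Among the genes that rose, Clic5, which encodes a chloride intracellular channel protein, went from 22.96 ± 5.84 to 96.6 ± 0.16 CPM, a 4.21-fold difference (log2 fold change 2.07, SE 0.16, adjusted p = 0.00729; chromosome 17, 44188584 to 44280172). Rcan2, a regulator of calcineurin that lies 0.149 Mb from Clic5 (chromosome 17, 43801351 to 44039516), rose from 10.99 ± 1.58 to 34.2 ± 4.003 CPM (1.60, SE 0.15, adjusted p = 0.0199). D3Ertd751e rose from 2.71 ± 0.57 to 10.0 ± 0.99 CPM (1.72, adjusted p = 0.0357). Gm8909, a gene of the class I histocompatibility region of chromosome 17 (36164443 to 36168537), had no reads in either control and 3.45 ± 0.72 CPM in the knockouts, at least 16.4-fold above a floor of 3 reads per library (0.21 CPM; adjusted p = 0.0224). Gm8909 was named after its values were seen, and its reads can be shared with paralogs. The transcript listed as Tdtomato, a red fluorescent protein, rose (adjusted p = 0.0236) from 0.52 and 6.02 CPM in the controls to 270 and 870 CPM in the knockouts, corresponding to 8, 86, 4098 and 16011 reads. The spread of this transcript within each genotype exceeded counting error, with 95% Poisson intervals, covering counting error only, of 262 to 279 CPM in knockout 1 and 857 to 884 CPM in knockout 2. The next higher genes under the naming rule did not pass with limma. Xpo5, a nuclear export receptor, was at 58.2 ± 1.87 CPM in controls and 93.9 ± 6.09 CPM in knockouts (adjusted p = 0.0698), and Akr1c18, an aldo-keto reductase, was at 115 ± 4.32 and 172 ± 12.4 CPM (adjusted p = 0.124), and both passed with DESeq2 (adjusted p = 0.000562 and 0.00268).

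**Figure D1:**
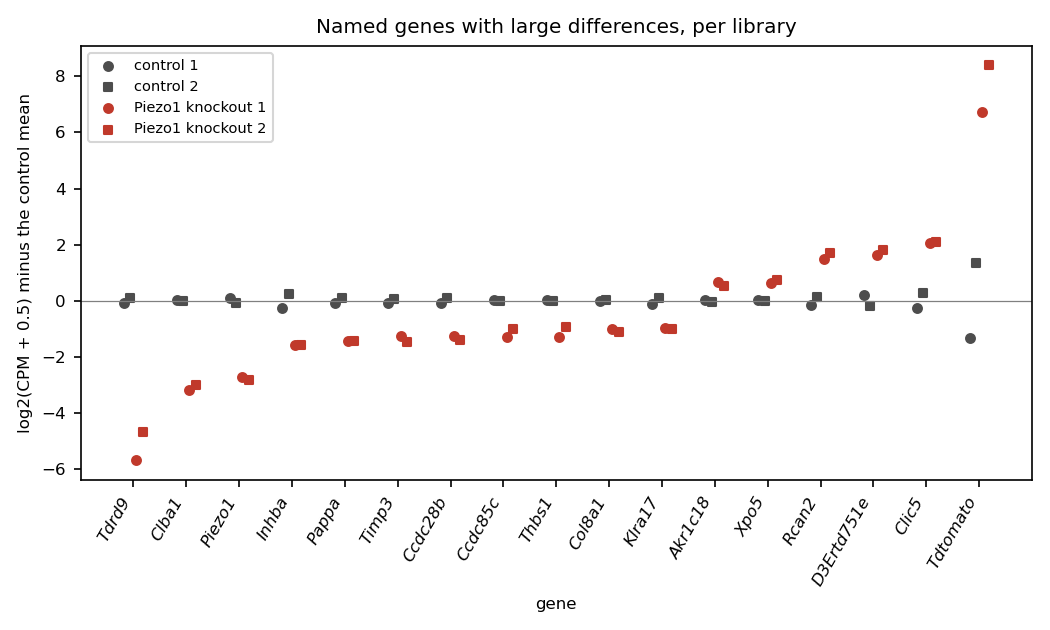
Values of named genes with large differences in each library, on the vertical axis as log2(CPM + 0.5) minus the control mean, with controls in grey and knockouts in red and 1 point per library. Every plotted gene had both knockout libraries on the same side of both controls, which the naming rule required. Xpo5 and Akr1c18 did not pass with limma, and Tdtomato had the widest spread within a genotype.

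The number of genes called depended on which 3 libraries were used: 7 genes passed without control 1, 8 without control 2, 76 without knockout 1 and 61 without knockout 2, and Piezo1, Tdrd9, Clba1, Clic5 and Tdtomato passed in each of these fits. When the variance was modelled without an intensity trend, 4 genes passed, among them 3 of the 19 (Piezo1, Clba1 and Gm8909), Tdtomato also did not pass under a robust variance model (adjusted p = 0.781), and with 2 libraries per genotype an exact permutation test of 1 gene cannot go below p = 0.333.

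No landmark gene of the osteoclast programme passed the test. The 12 genes were all measured, and 0 passed with limma, edgeR or DESeq2, with 1 at an unadjusted p under 0.05. That gene was Dcstamp, a membrane protein required for cell fusion, at 658 ± 11.8 CPM in controls and 857 ± 27.5 CPM in knockouts (log2 fold change 0.38, 95% confidence interval 0.15 to 0.61, adjusted p = 0.475). Acp5, the tartrate-resistant acid phosphatase, was at 9576 ± 395 and 10624 ± 2306 CPM, and Ctsk, the collagen-degrading cathepsin K, was at 23442 ± 541 and 25116 ± 2177 CPM. Nfatc1, the transcription factor that drives the programme, was at 850 ± 108 and 886 ± 212 CPM, and Mmp9 was at 20560 ± 1792 and 24103 ± 4554 CPM. Among the confidence limits of the 12 log2 fold changes the lowest was −0.66, for Ocstamp, and the highest was 0.84, for Mmp9. Single genes had narrower intervals, such as −0.07 to 0.41 for Tnfrsf11a, and differences inside a gene's own interval were not excluded. Itgb3, Calcr, Oscar, Atp6v0d2, Tnfrsf11a (which encodes the RANKL receptor) and Csf1r (the M-CSF receptor) each had an adjusted p of 0.9997. Of the 28 genes of the wider osteoclast list, 0 passed when adjusted over the list alone or over all genes, 1 had an unadjusted p under 0.05, and the list was not called (median log2 fold change 0.05, camera adjusted p = 0.0754). The macrophage identity list of 22 genes was not called either (median 0.12, adjusted p = 0.0505), with 0 members passing in limma and edgeR, 1 at an unadjusted p under 0.05 and 1 called by DESeq2. That member was the lipid carrier Apoe, at 930 ± 101 CPM in controls and 1346 ± 251 CPM in knockouts (limma adjusted p = 0.681).

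Markers of stromal and connective tissue cells formed the list with the smallest p in camera with the preset correlation. Of 21 tested markers of stromal, fibroblast and osteoblast cells, 11 fell and 10 did not pass when adjusted over the list alone, and over all genes limma called 1, Fbn1, and DESeq2 called 10, all lower. The median log2 fold change was −0.57, with 18 members negative and 3 positive (camera adjusted p = 3.36e-16; adjusted p = 0.49 with an estimated correlation). Sparc, a collagen-binding glycoprotein of bone, fell from 220 ± 10.8 to 147 ± 7.06 CPM, Tagln, an actin-binding protein of contractile cells, from 20.6 ± 2.19 to 10.3 ± 1.93 CPM, and the fibrillar collagen gene Col5a1 from 201 ± 39.0 to 117 ± 5.16 CPM, with list-alone adjusted p of 0.00285 each. Against the control mean, the list's median was −0.098 and 0.098 in the controls and −0.487 and −0.553 in the knockouts.

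Targets of the mechanically regulated co-activators YAP and TAZ were lower by list median, and the list was called in camera with the preset correlation only. Of 20 tested, 4 fell and 16 did not pass when adjusted over the list alone, and over all genes limma called 1, Ccn2, and DESeq2 called 3, all lower. The list's median log2 fold change was −0.29 (camera adjusted p = 6.01e-06; adjusted p = 0.49 with an estimated correlation). Ccn2 fell from 102 ± 11.6 to 51.2 ± 0.80 CPM, Ccn1, a related matricellular gene, from 34.8 ± 2.80 to 20.7 ± 1.06 CPM, Ankrd1 from 10.3 ± 3.88 to 3.29 ± 1.57 CPM, and the DNA-binding partner Tead1 from 11.1 ± 1.18 to 6.58 ± 0.39 CPM, with list-alone adjusted p of 0.000509, 0.00383, 0.0166 and 0.0173. Of 25 matrix proteases and remodelling genes, 5 fell and 20 did not pass when adjusted over the list alone, and over all genes limma called 1, Timp3, and DESeq2 called 5, all lower (median −0.10, camera adjusted p = 0.000155; adjusted p = 0.49 with an estimated correlation). The members that fell were not proteases. Timp3 and Timp1 inhibit metalloproteinases, Fn1 encodes fibronectin, and Lox and Loxl2 cross-link collagen. Fn1 went from 1442 ± 253 to 783 ± 17.5 CPM, Timp1 from 27.0 ± 0.86 to 12.4 ± 2.84 CPM, and Loxl2 from 42.1 ± 7.99 to 21.9 ± 5.74 CPM. Without knockout 2 the median of the matrix list was −0.0008, with a camera adjusted p of 0.0133, and without knockout 1 it was −0.40. The stromal markers were lower in the same knockout libraries. The design makes this unavoidable for lists that fall, so it is no sign of a shared cause.

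**Figure D2:**
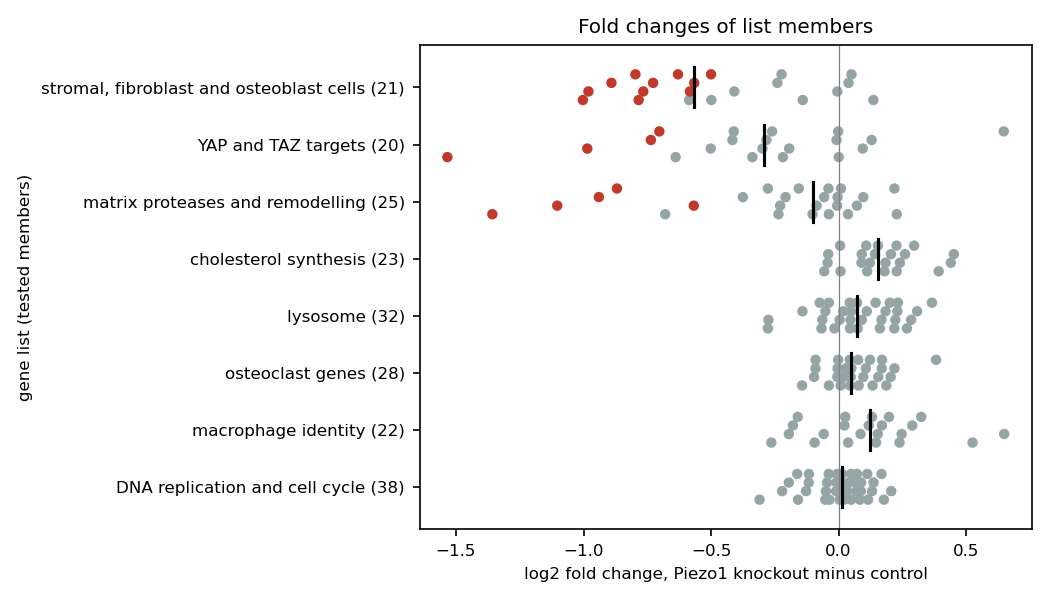
Log2 fold changes (knockout minus control, horizontal axis) of the tested members of 8 gene lists, with 1 point per gene, the number of members in brackets and a black bar at the median. Red points had an adjusted p under 0.05 over the list alone and grey points did not. Red points occurred in the stromal, YAP and TAZ and matrix lists, all at negative fold changes.

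Other called lists moved by small amounts, and 0 of their members passed in limma, edgeR or DESeq2. Cholesterol synthesis genes had a median log2 fold change of 0.15 (0.10 to 0.27 with 1 library left out), with 20 of 23 positive and 3 at an unadjusted p under 0.05 (camera adjusted p = 1.15e-05; adjusted p = 0.749 with an estimated correlation). Examples were Hmgcs1, which makes HMG-CoA, at 129 ± 3.83 CPM in controls and 155 ± 6.13 CPM in knockouts, and the sterol carrier Stard4 at 19.5 ± 2.11 and 26.5 ± 0.29 CPM. Lysosome genes had a median of 0.07 over 32 members, 3 of them at an unadjusted p under 0.05 (camera adjusted p = 0.00358; adjusted p = 0.531 with an estimated correlation), with the glycosidase Man2b1 at 233 ± 7.63 and 300.4 ± 12.0 CPM. Without control 2 or without knockout 1 the lysosome list had adjusted p of 0.194 and 0.0794. The 21 RANK and NF-kB signalling genes had a median of 0.09, with 0 at an unadjusted p under 0.05 (camera adjusted p = 0.0274; adjusted p = 0.757 with an estimated correlation), and the adjusted p was 0.278 without control 2 and 0.461 without knockout 2. Nfkbie, an inhibitor of NF-kB, was at 37.2 ± 4.27 and 44.1 ± 0.93 CPM. The 5 tested erythroid and megakaryocyte markers had a median of 0.22 (0.20 to 0.47 with 1 library left out), with 1, the beta-globin gene Hbb-bs, at an unadjusted p under 0.05 (camera adjusted p = 0.0285; adjusted p = 0.749 with an estimated correlation). Their adjusted p was 0.26 without control 1 and 0.123 without knockout 1, and Car2 in this list is also an osteoclast gene.

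Transcripts of the translation machinery and of the mitochondrial genome were lower by list median. Cytosolic ribosomal protein genes had a median log2 fold change of −0.09, with 33 of 34 negative, 0 passing and 2 at an unadjusted p under 0.05 (camera adjusted p = 2.01e-05; adjusted p = 0.757 with an estimated correlation). Rpl32 was at 191 ± 6.14 CPM in controls and 158 ± 8.29 CPM in knockouts, and without control 2 the list's median was 0.02, with an adjusted p of 0.656. The 11 mitochondrially encoded transcripts had a median of −0.41, with all 11 negative, 0 passing and 1 at an unadjusted p under 0.05 (camera adjusted p = 0.0021; adjusted p = 0.757 with an estimated correlation). mt-Nd1, a subunit of respiratory complex I, was at 2813 ± 483 and 2159 ± 1040 CPM. This list rested on knockout 1, the library with the lowest mitochondrial share. Without knockout 1 the median was 0.11 (adjusted p = 0.154), and without control 1 it was −0.22 (adjusted p = 0.26).

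The remaining 26 lists were not called, with camera adjusted p between 0.0505 and 0.876. In the calcium, calcineurin and NFAT list of 26 genes, 1, Rcan2, rose over the list alone and over all genes (list adjusted p = 0.387), and Nfatc2 was at 8.32 ± 2.75 CPM in controls and 4.203 ± 0.87 CPM in knockouts (adjusted p = 0.697). Among 22 type I interferon response genes 0 passed in limma, edgeR or DESeq2 and 1, Rtp4, had an unadjusted p under 0.05 (list adjusted p = 0.226). Among 38 DNA replication and cell cycle genes 0 passed with these tools and 0 had an unadjusted p under 0.05 (list adjusted p = 0.785). Csf1, which encodes M-CSF, fell within the list of inflammatory cytokines and chemokines when adjusted over the list alone, from 45.8 ± 0.76 to 30.5 ± 2.52 CPM, and did not pass over all genes (adjusted p = 0.196). In the list of osteoclast-derived coupling factors, adjusted over the list alone, Efnb2, a membrane ligand that signals to osteoblasts, rose from 69.4 ± 5.87 to 92.2 ± 0.29 CPM and Ccn1 fell, and neither passed over all genes with limma (adjusted p = 0.415 and 0.124), while Ccn1 passed with DESeq2 (adjusted p = 0.0122). With an estimated correlation between genes 0 of the 35 lists were called, with 3 at an unadjusted p under 0.05, and fry called 0, also with 3. Estimated correlations were above the preset 0.01 in the mitochondrially encoded (0.996), ribosomal (0.516), cholesterol (0.209), stromal (0.104) and RANK (0.074) lists. The preset may therefore overstate the calls of these lists. Those of the YAP and TAZ, matrix, lysosome and erythroid lists were −0.011, −0.017, −0.004 and −0.231, below the preset. For the lists below the preset, the size of the correlation therefore does not account for the loss of the call. In the simulated reads, with independent genes, a truly shifted list was also missed with an estimated correlation (camera adjusted p = 0.163). Losing a call in that setting therefore does not show that a list is unchanged. In 6 of the lists that were not called, the median, the mean and the camera direction differed in sign.

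Some of the genes that differed lay close together. By the positions of GENCODE release M21, chromosomes 12 and 17 each carried 3 of the called genes, Tdrd9, Clba1 and Ccdc85c on the former and Clic5, Rcan2 and Gm8909 on the latter. In a scan of 210 tiles of 10 Mb, added after the called genes had been seen, 3 held more genes at an unadjusted p under 0.01 than the genome-wide 170 of 11673 would give (hypergeometric test). On chromosome 17 these were 13 of 148 genes from 30000001 to 40000000, 8 of them higher and 5 lower (adjusted p = 4.88e-05), and 6 of 71 genes from 40000001 to 50000000 (adjusted p = 0.04). On chromosome 6 they were 7 of 82 genes from 120000001 to 130000000, among them Klra17 and the cyclin gene Ccnd2 (adjusted p = 0.0196). Without the called genes 1 of these 3 tiles kept its excess, the first (12 of 147, adjusted p = 9.72e-05), while the other tile of chromosome 17 and that of chromosome 6 did not (adjusted p = 0.603 and 0.0679). Without histocompatibility and nearby unnamed genes the first tile held 1 of 123 (unadjusted p = 0.815). The tile with Tdrd9 and Clba1 held 4 of 54 (adjusted p = 0.328), and the 37 other genes within 1 Mb of this pair had a median log2 fold change of 0.02, with 0 called and 1 at an unadjusted p under 0.01. Histocompatibility genes can share reads with near-identical paralogs, which was not examined here, so single values in the first of these tiles are uncertain.

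**Figure D3:**
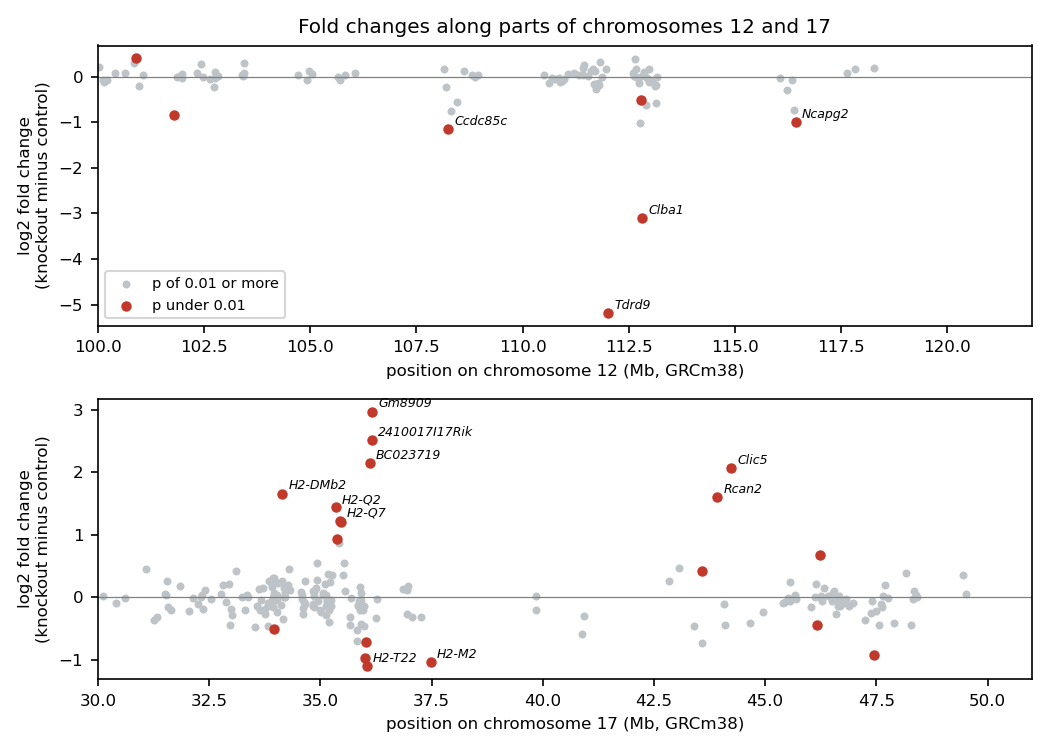
Log2 fold changes (knockout minus control, vertical axis) of tested genes by position in Mb (GRCm38, horizontal axis) along parts of chromosomes 12 (top) and 17 (bottom), with 1 point per gene, red at an unadjusted p under 0.01 and grey otherwise. Tdrd9 and Clba1 stand below their neighbours, and Clic5 and Rcan2 stand above theirs.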

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

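No test in this part was chosen after its result was seen. Piezo1 kept its fall past the threshold under every alternative, with a log2 fold change of −2.87 to −2.71 over the fits that left out 1 library. Over those fits the genes called higher numbered 2 to 16, those called lower 4 to 60 and the lists called 9 to 14. The lone library of a genotype is then assumed to vary like the other genotype. Fits without 1 control kept 7 (control 1 out) or 6 (control 2 out) of the 19 genes, and fits without 1 knockout kept all 19. Without the intensity trend 2 genes were higher and 2 lower, and with DESeq2 10 were higher and 56 lower. The cause was not tested. Pseudocounts of 1 and 0.1, no filter, the median-of-ratios and quantile scalings and edgeR kept all 19 genes. A mean of 5 CPM or more left Gm8909 untested, and the robust variance model lost Tdtomato. camera with an estimated correlation called 0 lists and fry 0. Quantile normalization ended the calls of the lysosome (adjusted p = 0.0567) and RANK (0.105) lists, no filter that of the erythroid list (0.0592), and no intensity trend that of the RANK list (0.0593). The robust model was not run for lists, since camera has no such option.

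Control and knockout libraries share only replicate numbers. Deviations of same-numbered libraries from their group means had a correlation of −0.0016 across genes. With a replicate block 18 genes were higher and 71 lower, all 19 genes among them, and the RANK list lost its call (adjusted p = 0.0601).

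Signs changed for genes that had not passed. Ctsk was at −0.074 under quantile normalization. With 1 library left out, log2 fold changes spanned −0.41 to 0.34 for Ocstamp, −0.39 to 0.84 for Itga2b, −0.20 to 0.29 for Nfatc1, −0.11 to 0.42 for Itgb3, −0.97 to 0.052 for mt-Nd1, −1.45 to 0.11 for mt-Nd4, −0.013 to 0.43 for Aurka, −0.090 to 0.36 for Acp5, −0.11 to 0.15 for Atp6v0d2 and −0.044 to 0.29 for Oscar. The median of the mitochondrially encoded list spanned −0.88 to 0.11, and that of the cytosolic ribosomal list −0.21 (without control 1) to 0.021 (without control 2). Over all alternatives, 1103 values of the other named genes kept their direction and side of the threshold, 42 lost the threshold, 35 gained it and 14 changed sign. For called lists these counts were 93, 30, 0 and 2. Depth limits the low genes: the floor of 3 reads used for genes without reads in the controls was 0.21 CPM.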

Other observations

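Chosen after results had been seen were the gene families, the spread of stromal folds, the use of the planned fits without either knockout library as a test of 1 deviating library, the paralog test in the tile that holds the paralogs and the count over other splits, while the length and GC, linked variant, copy number and first paralog tests were written beforehand. Families of the extracellular matrix and contractile apparatus, which share members such as Col1a1, Tagln and Loxl2 with the fixed stromal and matrix lists and partly restate them, were lower in the knockout libraries under TMM, median-of-ratios and quantile scaling. Of 30 collagen genes, 21 were lower, 11 of them at an unadjusted p under 0.05 and none in the other direction, with a median log2 fold change of −0.24 (camera adjusted p = 2.55e-08 over 5 families; adjusted p = 0.101 with an estimated correlation). Over all genes limma called 1 collagen gene, Col8a1, and DESeq2 called 7, all lower. All 8 smooth muscle contractile genes were lower, with a median of −0.68 (camera adjusted p = 9.5e-12; adjusted p = 0.101 with an estimated correlation), and limma called 0 of them over all genes and DESeq2 called 4. Cnn1, which encodes calponin, was at 12.5 ± 0.66 CPM in controls and 5.43 ± 1.70 CPM in knockouts, and Myl9, a myosin light chain, at 15.3 ± 2.24 and 8.90 ± 0.55 CPM. All 5 lysyl oxidase genes, which cross-link collagen, were lower (median −0.57; adjusted p = 0.101 with an estimated correlation), with 0 called by limma and 3 by DESeq2, and so were all 3 thrombospondin genes, with 1 called by limma and 2 by DESeq2 and Thbs2 at 68.4 ± 1.53 and 39.5 ± 8.17 CPM.

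Histocompatibility genes on chromosome 17 went in both directions. Of 19 tested, 7 were higher and 4 lower at an unadjusted p under 0.05, and over all genes limma called 0 and DESeq2 called 2, H2-T22 and H2-T23. The 4 lower genes at that unadjusted p were H2-T22, H2-T23, H2-T24 and H2-M2, with H2-T22 at 12.5 ± 1.23 CPM in controls and 5.63 ± 1.42 CPM in knockouts. H2-T24 and H2-M2 were not called by limma, edgeR or DESeq2. H2-Q4 was at 7.66 ± 1.74 and 14.97 ± 1.58 CPM, and H2-DMb2 at 0.035 ± 0.049 and 1.19 ± 0.09 CPM. Near Gm8909, the transcript 2410017I17Rik had 0 reads in both controls and 2.54 ± 1.44 CPM in the knockouts, and did not pass with limma (adjusted p = 0.109). Klra17 lies on chromosome 6 at 129831154 to 129876672, in a tile that also held Ccnd2, which encodes cyclin D2, at 40.6 ± 6.15 and 23.9 ± 3.69 CPM (adjusted p = 0.264).

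A smaller share of stromal cells in the knockout cultures may contribute to the lower matrix transcripts. The most abundant stromal markers, Col1a2 and Col1a1, were at 742 ± 88.8 and 660 ± 139 CPM in controls and 479 ± 38.9 and 375 ± 15.1 CPM in knockouts, and the list shares 0 genes with the other lists. The folds of 17 markers differed beyond replicate error (n = 17 markers, simulated p = 0.0228 with errors taken as independent between genes, range −1 to 0.05 around a common −0.62), with Cxcl12 at 33.8 ± 1.12 and 35.6 ± 11.7 CPM. This spread cannot decide on a uniform loss of such cells. Markers also transcribed by other cells of the culture would fall less, and the list's estimated correlation of 0.104 departs from independent errors. They also argue against length or GC bias (camera adjusted p = 5.95e-15 and median −0.57 after removing those trends) and against 1 deviating knockout library (largest adjusted p = 2.58e-10 with either left out). A uniform loss of stromal cells stays open. A change in the kind or state of the stromal cells, and an effect of Piezo1 loss on transcription in the monocytes, also stay open and were not tested.

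Tiles of chromosomes 6 and 17 held more genes at an unadjusted p under 0.01 than the genome-wide share would give. A gain or loss of DNA across most of a tile is argued against by tile medians, the farthest from 0 being −0.056, while 1 across fewer genes was not tested and stays open. Linked variants, carried in with a differing strain background, and reads shared between histocompatibility paralogs are candidate explanations that cannot be told apart in the chromosome 17 tile from 30000001 to 40000000, since both would act through the same genes: the tile held 12 of 147 without the called genes (adjusted p = 9.72e-05) and 1 of 123 without histocompatibility and nearby unnamed genes (adjusted p = 1). The other tiles were not called without the called genes (adjusted p = 0.603 on chromosome 17 and 0.0679 on chromosome 6), and the paralog test written beforehand (adjusted p = 0.0412) decides nothing, because the tile that gave it, from 40000001 to 50000000, held none of the genes removed. The strain background is not given in the sources used here, and an effect of the genotype on these genes stays open.

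The transcript listed as Tdtomato differed 3.22-fold between the knockout libraries and 11.6-fold between the controls, and knockout 1 was 44.9-fold above control 2. The labels name no reporter allele. Within 5 Mb on either side of Piezo1, 1 of 91 genes had an unadjusted p under 0.01. Of the 3 splits of the 4 libraries into 2 and 2, 1 gave as many as the real 19 genes, itself, and the highest of the others gave 2. So few splits cannot give a share under 0.05.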
